A study of Mus musculus with 3 samples.

How the data were processed

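Tail tendon derived stem cells of C57BL/6 mice, 1 WT library and 2 DF508 libraries, were collected at passage 4 when confluent, and their poly(A) RNA was sequenced, per the labels. Alignment and quantification used Bowtie and RSEM with the mm9 genome, per the submitters' processing notes; versions and the annotation release are not given in the sources used here. Each library has its own table, with no pooling. Per the file headers each table holds, for a gene, the expected count as deposited (RSEM's estimate of the reads from it, not normalized), the FPKM as deposited (fragments scaled to gene length and library size, by the authors) and the gene length that RSEM used. A table lists only genes with an estimate above 0, and a gene missing from a library was set to 0 there. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart.

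Of the expected counts, 79.8%, 79.4% and 79.7% were whole within 0.005. A gene whose estimate was not whole in at least 1 library shares reads with another gene or copy, and such genes are called uncertain. Expected counts were rounded to whole numbers. Gene IDs were matched to symbols with a RefSeq gene table of assembly GRCm38.p6, used only for names and for which genes neighbour each other. Of 16621 IDs 16579 matched (99.7%); the other 42 held 0.16% to 0.17% of the counts and were kept under their IDs. No coordinates are given, since the files use another build.

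The totals were 5298326, 5241826 and 5246886 counts. A count of 0 allows up to 3 counts, or 0.579, 0.568 and 0.566 CPM in WT and DF508 replicates 1 and 2, on the normalized library sizes. The labels describe no molecular identifiers, so intervals and floors cover counting error only.

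The design, the tests, the gene lists and the rule for named genes were fixed before the data were examined. Genotype was compared with edgeR's quasi-likelihood test on TMM-normalized counts, after edgeR's filterByExpr, which for a smallest group of 1 library keeps a gene that passes in any library, with the 3 libraries and genotype as the sole term; adjusted p-values are Benjamini-Hochberg and the threshold is 0.05. The fit has 1 residual degree of freedom, from the DF508 pair, and 7.7 prior degrees of freedom shared across genes. The standard error of a log2 fold change is its size over the square root of the F statistic. Log2 CPM used a prior count of 2. Beside the test stands a count of genes at least 2-fold from WT in both DF508 libraries with a mean of at least 1 CPM.

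In total 35 gene lists were written for tendon biology, CFTR and the cell types a tendon culture could hold; 749 of their 819 genes matched. The 31 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over lists. Each list's median was also ranked, as a percentile, among 10000 random lists of its size matched on mean expression. That percentile ignores correlation between genes and is given for the matrix and lineage lists. No list was called with an estimated correlation or in fry's directional test, which leave 1 residual degree of freedom; fry's mixed test, for change in either direction, called 4 lists.

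The genes named are Cftr; the 12 highest and 12 lowest by fitted fold change among those past the threshold, with a mean of at least 5 CPM and at least 2-fold from WT the same way in both DF508 libraries; up to 4 members of each list past the threshold by fold change, or up to 2 by level where none passed; and the sex-linked genes. Genes named outside this rule are said to be so.

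Alternatives were DESeq2 size factors, upper-quartile factors, no filter, a mean of at least 50 counts, DESeq2's Wald test, limma-voom, edgeR's likelihood ratio test, edgeR's glmTreat against a fold of 1.2, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 1 or no filter, and each DF508 library left out. For lists they were an estimated correlation, fry, ranks, size factors, no filter and FPKM. After the data were seen, a fit without genes sharing reads and the size rule with each DF508 library as the lone one were added. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

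The test was run on simulated counts for the 12888 genes of this comparison, with 100 genes changed at each fold and 3 simulations. Changed genes were drawn only from those with a mean of at least 5 CPM. The test recovered 37% of 2-fold and 73% of 4-fold changes, with 3 false calls on average. A list shifted by 1.5-fold in counts simulated for 12681 genes was called and 0 of 30 random lists were. Genes were simulated independently of each other, so this does not show how often lists of correlated genes are called falsely.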

Results

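Poly(A) RNA was sequenced from tail tendon derived stem cells of C57BL/6 mice, with an age of 10 weeks in the labels of every library. These are colony-forming progenitor cells isolated from tendon and grown in culture, here collected at passage 4 without treatment. There were 3 libraries. Of these, 1 came from wild-type cells (WT) and 2 from cells with the ΔF508 mutation of Cftr (DF508). Cftr encodes an anion channel of epithelial cells, and ΔF508, the loss of a phenylalanine, is the most common mutation in cystic fibrosis. The total estimated count was 5298326 in the WT library, 5241826 in DF508 replicate 1 and 5246886 in DF508 replicate 2. The libraries listed 15346, 15444 and 15474 genes with an estimate above 0. The labels do not say whether the DF508 libraries came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. The WT library had no replicate and was assumed to vary like the DF508 pair.

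Cftr itself (gene ID 12638) was close to the limit of detection. It had 15 counts in the WT library and 1 count in each DF508 library, or 2.89, 0.189 and 0.189 CPM, the count scaled to library size. The ratio of DF508 to WT was 0.0653, with an exact 95% Poisson interval of 0.00725 to 0.281 that covers counting error only. In the model across all genes the log2 fold change was -3.78 ± 1.1 (SE), and the gene did not pass the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.185). ΔF508 is a short in-frame deletion, so the transcript level does not check which library carries it.

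The comparison of DF508 with WT asked which transcripts differed between mutant and wild-type tendon cells. In DF508, the lists of G2 and M phase genes, S phase genes and smooth muscle and pericyte markers were higher, and those of immediate early, glycolytic and hypoxia, and interferon-stimulated genes were lower, together with the collagenase Mmp13 and several chemokines. These 6 lists passed in camera with a preset correlation and none with an estimated correlation (adjusted p = 0.718 to 0.871) or in fry's directional test (adjusted p = 0.271), and in the G2 and M, S phase, glycolytic and interferon lists most members did not pass singly. Camera with an estimated correlation leaves 1 residual degree of freedom, and its lowest adjusted p over all 31 lists was 0.718. Of 12888 genes tested, 63 rose and 116 fell in DF508. All 179 moved the same way from WT in both DF508 libraries; 22 rose and 30 fell by at least 2-fold. Of the 179, 53 share reads and are uncertain. A fit without genes that share reads called 71, all among the 179, so some calls on genes that share no reads were lost too. Tested against a fold of 1.2, edgeR's glmTreat called 58. At an unadjusted p under 0.05 there were 1538 genes, where chance alone gives 644 if the WT library varied like the DF508 pair. The count depended on the model: DESeq2's Wald test called 65 genes (62 of them among the 179), edgeR's likelihood ratio test 403, and edgeR without a filter on low counts or limma on log2(FPKM + 1) none, with 1123 and 1145 genes at an unadjusted p under 0.05. In simulations with no changed gene the test called 0 to 5 genes, but 67 to 526 when the WT library was given a dispersion 4 times that of the DF508 pair, a range that holds the observed count. In that case 2272 genes on average had an unadjusted p under 0.05 with no gene changed, more than the 1538 observed.

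**Figure D1:**
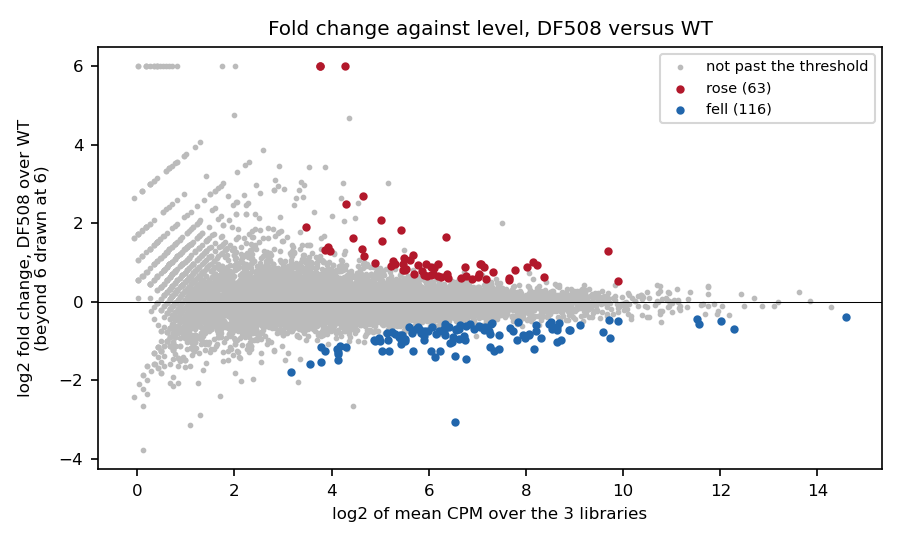
Each point is 1 of the 12888 genes tested; the x axis gives log2 of the mean CPM over the 3 libraries and the y axis the fitted log2 fold change of DF508 over WT, with values beyond 6 drawn at 6. Red points are the 63 genes that rose and blue points the 116 that fell; the isolated blue point at -3.07 is Mmp13.

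The distances between libraries gave a weaker separation. Over 12884 genes with a mean of at least 1 CPM, the SD of the log2 difference was 0.458 between WT and DF508 replicate 1, 0.531 between WT and replicate 2, and 0.45 between the DF508 libraries. The scaled median absolute deviation, on which extreme genes weigh less, was 0.284, 0.297 and 0.234 for these pairs. Pearson correlations across genes, which are not independent replicates, were 0.975, 0.966 and 0.975. By size alone, 174 genes were at least 2-fold higher and 75 at least 2-fold lower than WT in both DF508 libraries. The numbers were 77 and 31 at a mean of at least 5 CPM, and 251 and 290 at 0.1 CPM. Replicate 1 alone was 2-fold higher than WT in 289 and lower in 230 genes, and replicate 2 alone in 445 and 238. At a mean of at least 1 CPM DF508 replicate 2 stood as far from the other libraries by this rule, with 265 genes against 249 for WT, and replicate 1 less far, with 95. At a mean of at least 5 CPM the order turned, with 108 genes for WT, 80 for DF508 replicate 2 and 15 for replicate 1. The DF508 libraries differed from each other by more than counting noise, with a chi-square of 3.69 per degree of freedom over 12465 genes. They were therefore not taken for 1 library listed again, but this does not show that they came from separate cultures. Between WT and DF508 replicates 1 and 2 the chi-square per degree of freedom was 7.2 and 8.41.

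The largest fall among genes past the threshold was in Mmp13 (gene ID 17386), the collagenase that cleaves fibrillar collagen. Its level was 226 CPM in WT and 26.8 ± 1.4 CPM in DF508 (SD, n = 2), 8.4-fold lower (log2 fold change -3.07 ± 0.11 SE, adjusted p = 1.11e-05). The BMP ligand Gdf6, with 17.2 CPM in WT and 4.92 ± 1.08 CPM in DF508, was 3.48-fold lower, and the clock transcription factor Npas2 2.99-fold lower. The metallothioneins Mt1 and Mt2, which bind zinc and copper, were 2.77-fold and 2.42-fold lower. The sulfotransferase Chst15, which shares reads with another gene or copy and is therefore uncertain, was 2.54-fold lower, and the ATP-gated channel P2rx7 2.43-fold lower. The others among the 12 lowest were genes known to be induced by interferon. With DESeq2's Wald test Gdf6, Npas2, Chst15 and P2rx7 did not pass the threshold.

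Among the genes that rose, elastin, Eln (gene ID 13717), went from 4.82 CPM in WT to 27.2 ± 9.83 CPM in DF508, 5.62-fold higher (log2 fold change 2.49 ± 0.39 SE, adjusted p = 0.0222). The secreted BMP antagonist Grem1 (gene ID 23892) went from 10.2 to 43.1 ± 5.18 CPM, 4.21-fold higher (adjusted p = 0.00629). The retinoic acid hydroxylase Cyp26b1 was 3.12-fold, the uncharacterised AI593442 3.75-fold, the protease-like Prss35 6.48-fold and the NAD-synthesising enzyme Nmnat2 3.07-fold higher. Prss35 and Nmnat2 share reads and are uncertain. Prss35 had 35.1 ± 18.1 CPM in DF508, and its log2 difference from WT was 1.97 in replicate 1 and 3.06 in replicate 2. The predicted genes Gm4070, Gm4724 and Gm14434 had 0 counts in WT. Gm4070 had 134 and 172 counts in the DF508 libraries, and the others had the same estimates of 142 and 72 counts. Against a floor of 3 counts per library (0.579 CPM in WT), the most that a count of 0 allows, the mean DF508 levels were at least about 50-fold and 35-fold higher. All 3 share reads, so which copy the reads came from is uncertain. The 0 estimates in WT and these folds are therefore uncertain too. AI593442, Cyp26b1 and Nmnat2 did not pass with DESeq2's Wald test, nor Prss35, Eln, AI593442, Gm4724 and Gm14434 with limma-voom.

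**Figure D2:**
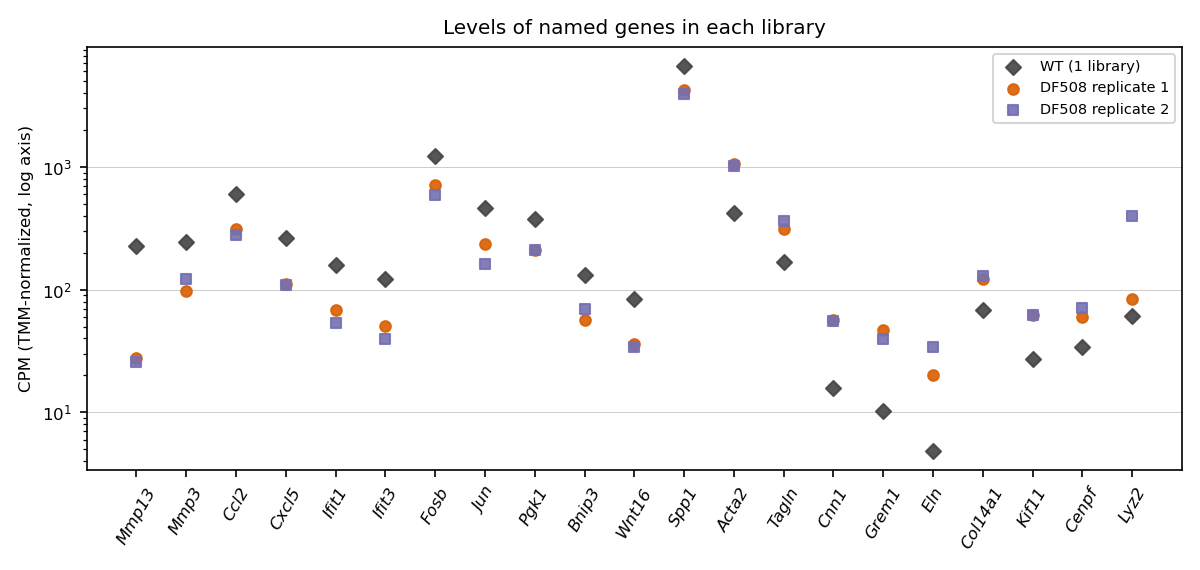
Normalised level of named genes in each library, in CPM on a log axis; each marker is 1 library, so no error bar is drawn. Mmp13 lies at 226 CPM in WT and at a mean of 26.8 CPM in DF508, Acta2 at 420 CPM in WT and a mean of 1037 CPM in DF508, and Lyz2 is high in DF508 replicate 2 alone.

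Genes of cell division were higher in DF508. Of 33 tested G2 and M phase genes, 10 rose, none fell and 23 did not pass; all 33 had a positive fold change, with a median log2 fold change of 0.68. Adjusted over the list alone, 28 rose. The mitotic kinase Aurkb was 2.6-fold, the spindle motor Kif11 2.28-fold (27.4 CPM in WT, 62.6 ± 0.147 CPM in DF508), the kinesin Kif20b 2.22-fold and the kinetochore protein Cenpf 1.91-fold higher; Kif11 and Cenpf share reads. Of 29 S phase genes, 3 rose and none fell, with a median of 0.56, 28 members positive and 11 that rose when adjusted over the list alone. These were the replicative helicase subunit Mcm3, 1.74-fold higher, and both ribonucleotide reductase subunits, Rrm2 1.56-fold and Rrm1 1.53-fold higher. Both lists rose in camera with a preset correlation (adjusted p = 6.51e-18 and 1.21e-11), and not with an estimated correlation (adjusted p = 0.871 and 0.718), which leaves 1 residual degree of freedom. The G2 and M medians were 0.64 in DF508 replicate 1 and 0.74 in replicate 2, where myeloid markers were also high (medians of 0.77 and 2.74). Of the genes named here Kif11 alone passed with DESeq2's Wald test, and Aurkb, Kif20b and Mcm3 did not pass with limma-voom.

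Several smooth muscle and pericyte markers rose as well. Of 8 tested smooth muscle and pericyte markers 4 rose and 4 did not pass, and the list had a median log2 fold change of 1.05 with all 8 positive; adjusted over the list alone 5 rose. The smooth muscle actin Acta2 (gene ID 11475) went from 420 CPM to 1037 ± 37.6 CPM, 2.47-fold higher (adjusted p = 0.00178). Acta2 shares reads with another gene or copy and is therefore uncertain. Calponin, Cnn1 (gene ID 12797), was 3.56-fold, Mustn1 2.94-fold and the actin nucleator Lmod1 2.04-fold higher. The list passed in camera (adjusted p = 1.42e-07) but not with an estimated correlation (adjusted p = 0.718). Of 29 YAP and SRF targets, genes that respond to mechanical tension, 5 rose, none fell and 24 did not pass, and 8 rose and 2 fell when adjusted over the list alone. Those that rose included Cnn1, Acta2, the actin-binding Tagln (2.02-fold) and the myosin light chain Myl9 (1.93-fold). This list had a median of 0.14 and a camera adjusted p of 0.0255 at the preset correlation. The adjusted p became 0.871 with an estimated correlation, which was 0.32 for this list, and 0.0818 on ranks. The list passed in fry's mixed test (adjusted p = 0.019). In the TGF-beta list 3 of 32 genes rose, Grem1, Acta2 and Tagln, as also when adjusted over the list alone, and the list did not pass (median 0.01, adjusted p = 0.61), except in fry's mixed test for change in either direction (adjusted p = 0.0494). Lmod1 did not pass with DESeq2's Wald test.

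Immediate early genes, which respond within minutes to serum and stress signals, were lower in DF508. Of 18 tested, 12 fell and none rose, with a median log2 fold change of -0.74 and 17 members negative, and 13 fell when adjusted over the list alone. Jun went from 459 to 199 ± 51.4 CPM (2.31-fold lower, adjusted p = 0.0193). The phosphatase Dusp1 was 1.98-fold, the mRNA-destabilising Zfp36 1.92-fold and Fosb 1.89-fold lower. The list passed in camera (adjusted p = 1.72e-10) and had an adjusted p of 0.718 with an estimated correlation. Jun did not pass with DESeq2's Wald test.

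Genes of glycolysis and the hypoxia response were also lower. Of 27 tested 9 fell and none rose, with a median of -0.42 and 25 members negative, and 19 fell when adjusted over the list alone. The glycolytic kinase Pgk1 went from 374 to 212 ± 1.03 CPM (1.77-fold lower, adjusted p = 0.00937), the mitophagy receptor Bnip3 was 2.08-fold, the regulator of glycolysis Pfkfb3, which shares reads, 2.2-fold and the lactate exporter Slc16a3 1.82-fold lower. The adjusted p was 8.98e-10 in camera and 0.718 with an estimated correlation. None of 35 oxidative phosphorylation genes passed, over all genes or adjusted over the list alone (median -0.09, adjusted p = 0.127). In the list of growth factors 3 of 30 fell, Gdf6, Angptl4 (1.82-fold) and Vegfa (1.5-fold, sharing reads), with 5 lower and 5 higher when adjusted over the list alone and no call for the list (median -0.12, adjusted p = 0.443). Pfkfb3, Slc16a3, Angptl4 and Vegfa did not pass with DESeq2's Wald test.

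Of 35 interferon-stimulated genes 9 fell and none rose, and 17 fell when adjusted over the list alone. The median was -0.42, with 26 members negative and 9 positive. The deISGylase Usp18 was 2.81-fold lower, with 30.9 CPM in WT and 11 ± 1.09 CPM in DF508. Ifit3, Ifit1 and Ifi44, which share reads, were 2.69-fold, 2.6-fold and 2.39-fold lower. The nucleic acid sensor Zbp1, also interferon-induced but outside the list, was 2.91-fold lower. The list passed in camera (adjusted p = 1.42e-07) and had an adjusted p of 0.718 with an estimated correlation. Zbp1 and Usp18 did not pass with DESeq2's Wald test.

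Several chemokines fell, although the NF-kB, cytokine and chemokine list did not pass as a whole. Of 31 tested members 6 fell and none rose; adjusted over the list alone 7 fell. Ccl2 went from 602 to 297 ± 21.7 CPM (2.03-fold lower, adjusted p = 0.00587), Cxcl5 was 2.38-fold lower, Cxcl14 1.96-fold and the stromelysin Mmp3 2.23-fold; Cxcl5 and Mmp3 share reads. The list had a median of -0.04, a mean of 0.03 and a direction of down in camera (adjusted p = 0.206), and passed in fry's mixed test (adjusted p = 0.0434). Its median was -0.13 in DF508 replicate 1 and 0.02 in replicate 2, where the myeloid markers stood highest.

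Matrix genes moved in separate ways. Among 26 matrix proteases and inhibitors 5 fell and none rose; adjusted over the list alone 7 fell and 2 rose. Besides Mmp13 and Mmp3 these included the aggrecanase Adamts5, 1.97-fold lower (626 CPM in WT, 317 ± 78.5 CPM in DF508), and Adamts1, 1.68-fold lower. The list did not pass (median -0.05, adjusted p = 0.0989). Of 24 collagens 1 rose, the fibril-associated Col14a1, from 68.3 to 126 ± 4.92 CPM (1.85-fold, adjusted p = 0.0112), and the list did not pass (median 0.13, adjusted p = 0.42; 3 rose when adjusted over the list alone). Of 27 proteoglycans and matrix glycoproteins, Eln and decorin, Dcn (1.43-fold), rose and fibronectin, Fn1 (1.31-fold), fell. Adjusted over the list alone, 8 were higher and 2 lower past the threshold (list median 0.14, camera adjusted p = 0.181). Among 22 genes of collagen crosslinking and processing 1 fell, the prolyl hydroxylase P4ha2, 1.58-fold (adjusted p = 0.154 for the list; 5 fell and 1 rose when adjusted over the list alone). Adamts5, Adamts1, Fn1 and P4ha2 did not pass with DESeq2's Wald test. Among random lists the percentiles of the medians were 15 for proteases, 99.7 for collagens, 100 for proteoglycans and 3.8 for crosslinking genes. Taken for DF508 replicates 1 and 2 singly, they were 1.7 and 0.4 for proteases and 96.9 and 70 for collagens. They were 100 and 100 for proteoglycans and 4.9 and 0 for crosslinking genes. The single medians were -0.12 and -0.18 for proteases and 0.08 and 0 for collagens.

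No list of tendon or other lineage genes passed in camera. Among random lists the medians stood at percentiles of 1 (tendon), 0.3 (osteogenic), 0.8 (adipogenic), 96.7 (chondrogenic), 38.3 (stem cell surface) and 16 (Hox). For DF508 replicates 1 and 2 singly, the percentiles were 0.3 and 63.4 for tendon genes and 15.4 and 0 for osteogenic genes. They were 0.1 and 6.1 for adipogenic and 95.8 and 67.9 for chondrogenic genes. For stem cell surface markers they were 72.2 and 16.3, and for Hox genes 24 and 48.7. Of 19 tendon lineage genes 2 fell, the transcription factor Egr2 (1.57-fold) and the matrix protein Cilp (1.36-fold), and 5 fell and 2 rose when adjusted over the list alone. The list had a median of -0.15, a mean of 0.05 and a direction of down, and its median was -0.19 in DF508 replicate 1 and 0 in replicate 2 (adjusted p = 0.216). Of 11 osteogenic genes 1 fell, osteopontin, Spp1, from 6618 to 4112 ± 207 CPM (1.61-fold, adjusted p = 0.00813), with 2 that rose and 1 that fell when adjusted over the list alone (median -0.32, list adjusted p = 0.359). The list median was -0.1 in DF508 replicate 1 and -0.74 in replicate 2, and the list passed in fry's mixed test (adjusted p = 0.0494). Of 13 adipogenic genes Cebpd fell, 1.62-fold, with 1 higher and 1 lower when adjusted over the list alone. The list had a median of -0.22, a mean of 0.11 and a direction of down in camera (adjusted p = 0.61). Its median was -0.37 in DF508 replicate 1 and -0.15 in replicate 2. None of 9 chondrogenic genes passed, and none when adjusted over the list alone (median 0.27, camera adjusted p = 0.61). That median was 0.25 in DF508 replicate 1 and 0.07 in replicate 2. Prg4 stood at 3788 CPM in WT and 3047 ± 252 CPM in DF508. None of 17 stem cell surface markers passed over all genes and 1 was lower when adjusted over the list alone (median -0.03, adjusted p = 0.61); Itgb1 stood at 1046 and 1027 ± 54.5 CPM. Of 27 Hox and positional genes none passed either way (median -0.05, mean 0.05, direction up, adjusted p = 0.922). Egr2 and Cebpd did not pass with DESeq2's Wald test.

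Signalling lists gave few calls. Among 25 Wnt ligands, receptors and modulators Wnt16 fell, from 83.3 to 35.1 ± 1.82 CPM (2.38-fold, adjusted p = 0.00587), and 1 rose besides when adjusted over the list alone; the list had a median of 0.02, a mean of -0.04 and a direction of down (adjusted p = 0.42). Among 17 Wnt/beta-catenin target genes Jun fell, in the list alone as well, and the list had a median of 0.11, a mean of -0.01 and a direction of up (adjusted p = 0.61). Of 21 ion channels and transporters linked to CFTR 1 fell, the proton-potassium ATPase Atp12a, from 369 to 194 ± 31.6 CPM (1.91-fold, adjusted p = 0.0191), and 2 fell when adjusted over the list alone (median -0.09, list adjusted p = 0.14). Of 25 oxidative stress genes 3 fell, Mt1, Mt2 and the heme oxygenase Hmox1 (1.43-fold), with 5 lower and 1 higher in the list alone (median -0.07, list adjusted p = 0.42). In the p53 and senescence list Btg2 fell, 1.79-fold, as 1 of 22, with 5 lower in the list alone (median -0.18, adjusted p = 0.0602). That median was -0.04 in DF508 replicate 1 and -0.37 in replicate 2. In the unfolded protein response list Ppp1r15a fell, 1.48-fold, as 1 of 26, with 2 lower in the list alone (median 0, mean -0.07, adjusted p = 0.443). None of 26 cholesterol and fatty acid genes passed in either way (median -0.01, adjusted p = 0.61). Hmox1 and Ppp1r15a did not pass with DESeq2's Wald test. Medians in DF508 replicates 1 and 2 were 0.02 and -0.14 for the Wnt ligand list and 0.22 and 0.02 for Wnt/beta-catenin targets. They were -0.14 and 0.01 for oxidative stress, -0.07 and -0.19 for ion channels, and 0.07 and -0.06 for the unfolded protein response.

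**Figure D3:**
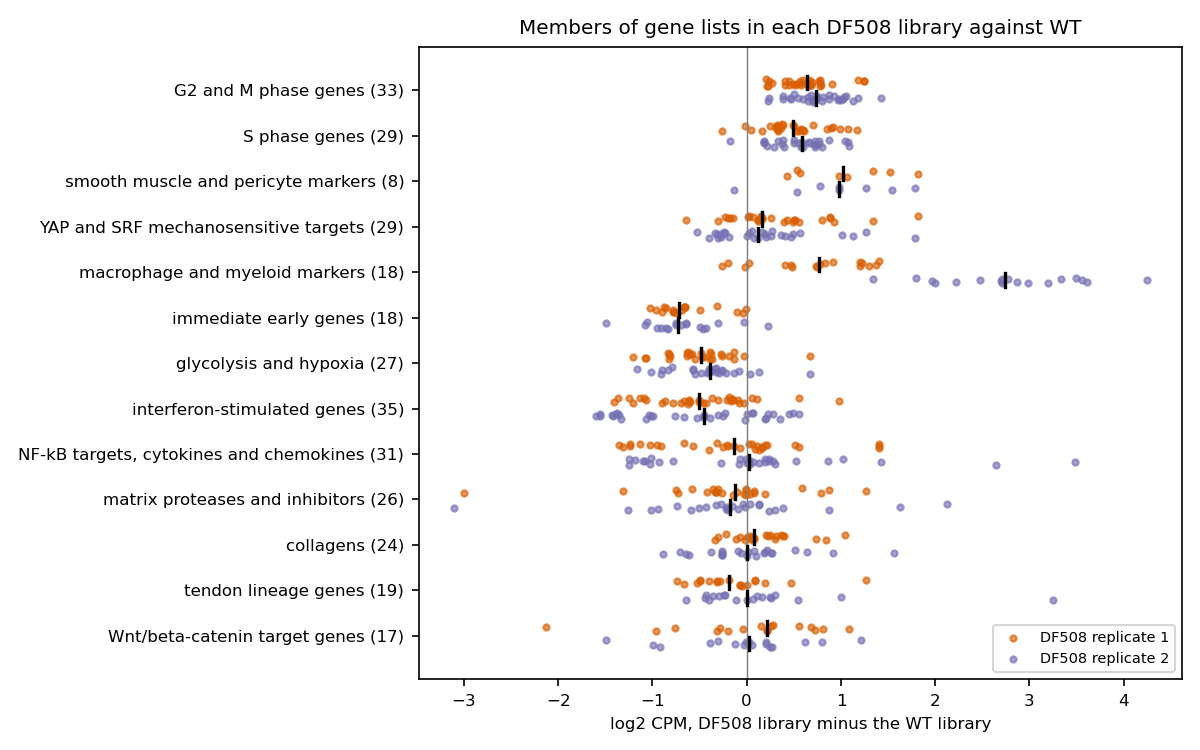
Each point is a gene of a list, placed by its log2 CPM in a DF508 library minus that in the WT library; black bars are list medians, orange is DF508 replicate 1, violet replicate 2, and the number of tested members stands in brackets. The G2 and M, S phase, smooth muscle and pericyte, immediate early, glycolytic and interferon lists have like medians in both DF508 libraries, and the myeloid list has medians of 0.77 and 2.74.

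Transcripts of other cell types were also followed. The summed level of the macrophage and myeloid markers was 115 CPM in WT, 174 CPM in DF508 replicate 1 and 808 CPM in replicate 2, or 7.01 times WT. None of 18 tested members passed over all genes, and 12 rose when adjusted over the list alone. As a list they rose in camera at the preset correlation (adjusted p = 0.000126). The median was 2.26, or 0.77 in DF508 replicate 1 and 2.74 in replicate 2. With an estimated correlation, which was 1 for this list, the camera adjusted p was 0.871. Lysozyme, Lyz2, which shares reads, had 314, 447 and 2118 counts. Of 20 complement and antigen presentation genes none passed either way. That list had a median of 0.05, a mean of 0.07 and a direction of down (adjusted p = 0.61). Its median was -0.2 in DF508 replicate 1 and 0.21 in replicate 2, and its members were higher in DF508 replicate 2 than in replicate 1 by a median log2 difference of 0.54, in the library with the high myeloid markers. Endothelial markers summed to 114, 110 and 98.9 CPM, skeletal muscle markers to 9.65, 11.9 and 9.06 CPM and keratinocyte markers to 14.5, 16.3 and 16 CPM; each of these lists had fewer than 5 tested members and was not tested. Schwann and neural markers summed to 44.4, 43.2 and 27.9 CPM, and none of 8 passed either way (median -0.09, adjusted p = 0.426). Their median was 0.04 in DF508 replicate 1 and -1.14 in replicate 2. Xist, expressed from the inactive X chromosome of female cells, had 6482, 7478 and 7218 counts, and the Y-linked Uty and Eif2s3y at most 1 count in any library.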

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

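Leaving out genes that share reads and setting each DF508 library against the rest were chosen after the data were seen. No paired analysis was possible because the WT library carries no replicate number and stands alone. Leaving out a DF508 library leaves 1 library against 1, with no residual degrees of freedom, so fold changes alone were recomputed. No called list median reversed. No named gene past the threshold could reverse here, since all 179 calls had the same sign in both DF508 libraries. None of the 179 calls reversed under any alternative, which is a weak check. Every alternative used the same 3 libraries, and the smallest called log2 fold change was 0.39 in size. Size factors, upper-quartile factors, a mean of at least 50 counts and limma-voom kept the counts within 1.5 times (lowest 52 rose, highest 137 fell). The counts of genes that rose and fell became 23 and 42 with DESeq2's Wald test, 182 and 221 with edgeR's likelihood ratio test, 21 and 37 against a fold of 1.2, and 19 and 52 without genes sharing reads. They were 0 and 0 in edgeR without a filter on low counts (1123 genes at an unadjusted p under 0.05) and 0 and 0 in limma on log2(FPKM + 1), log2(FPKM + 0.1) and unfiltered log2(FPKM + 1) (1145, 1159 and 1615 such genes). A null fold above 1 accounts by construction for part of the loss with glmTreat. Leaving out the 53 called genes that share reads accounts for part of the loss in the fit without them. That fit also lost calls on genes that share no reads. For this further loss and for the other settings the cause was not tested.

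The size rule gave 77 higher and 31 lower at a mean of 5 CPM. At 0.1 CPM it gave 251 higher and 290 lower, so the excess of higher genes depended on the CPM cut. With DF508 replicate 1 as the lone library it gave 68 and 27, and with replicate 2 85 and 180. Leaving out a DF508 library gave 289 to 445 higher and 230 to 238 lower, since 1 library then has to pass in place of 2. The SD between the DF508 libraries over the mean SD to WT was 0.91, and 0.85 at 5 CPM or 0.92 on FPKM. The Cftr ratio of 0.0653 ranged from 0.0652 to 0.0667. The numbers of lists that rose and fell, 5 and 3, became 0 and 0 with an estimated correlation and 0 and 0 in fry's directional test (lowest adjusted p 0.718 and 0.271), where 1 residual degree of freedom is left. On ranks 1 list was lost, the YAP and SRF targets (0.0818; 0.0219 to 0.871 over alternatives), and on FPKM 1 was gained, p53 targets (0.0356; 0.0356 to 0.871). Of the 63 named genes past the threshold, 29 lost their call with DESeq2's Wald test, 8 with limma-voom and all 63 with limma on FPKM. None reversed, which is a weak check for the reason given above. Depth limits genes as low as Cftr. The 37% recovery of simulated 2-fold changes holds for genes with a mean of at least 5 CPM and gives no rate for Cftr.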

Other observations

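Tests chosen after the result was seen were the other splits of the libraries, the macrophage test of the list medians, the WT culture test, the pericyte test and the test of the 20 genes nearest Cftr; the test of 40 genes near Cftr was set beforehand but had a condition added afterwards, and the tests of a length or level trend and of a second macrophage list were set beforehand.

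Some genes beside Cftr on its chromosome were lower in DF508. They are named here after their values were seen, and lie among the 20 tested genes nearest Cftr, of which 9 had an unadjusted p under 0.05 (45%, against 11.9% of other genes). Met, the receptor of hepatocyte growth factor, fell from 109 to 65.1 CPM (1.67-fold, edgeR adjusted p = 0.0269), and Wnt16 also fell. The other 7 did not pass the threshold over all genes. Cttnbp2 had 37 counts in WT and 4 and 10 in the DF508 libraries (adjusted p = 0.133). Capza2, Cav1, Cped1, Fam3c and Tmem106b were 1.25-fold to 1.31-fold lower, and Ing3 was 1.6-fold higher.

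A candidate explanation for these neighbours is a chromosome segment of another strain carried along with the mutation, and runs of 20, 40 and 80 genes were examined, of which 40 was the size set beforehand. With 40 neighbours the same 9 genes gave a two-sided Fisher exact p of 0.0488, which met the prediction as first written; a demand that under 5% of runs of 40 genes elsewhere hold as many was added afterwards and was missed, with 5.02% of 11996 runs. With 80 neighbours the Fisher exact p was 0.603. For a local effect on the 20 genes nearest Cftr, 0% of 12396 runs elsewhere held 9 such genes and the highest held 8, but that size was chosen for its result, so the strain segment and a local effect of the mutation both stay open. Sequence variants were not analysed here.

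Higher G2 and M, S phase and smooth muscle and pericyte lists, and lower immediate early, glycolytic and interferon lists, had like medians in both DF508 libraries, although none of these lists kept its call with an estimated correlation (adjusted p = 0.718 to 0.871). The ratio of medians, replicate 1 to 2, was at least 0.83 in the G2 and M, S phase, immediate early, glycolytic and interferon lists. It was 1.04 for the 8 smooth muscle and pericyte markers. These differences did not scale with the myeloid markers, whose medians over WT were 0.77 and 2.74 in replicates 1 and 2. This argues only weakly against macrophage RNA in replicate 2. The lists were grouped as changed in both libraries after their values were seen, and replicate 1 also held myeloid markers at 1.51 times WT. A trend with gene length or level is argued against for the 5 lists named first. At least 0.95 of each of their medians remained after the trend was subtracted. The trend was not tested for the smooth muscle and pericyte list. More smooth muscle cells or pericytes stay open for that list. Myh11, Des, Rgs5, Notch3, Cspg4 and Abcc9, named outside the rule and after their values were seen, together gained 16.7 CPM. That was 2.7% of the 617.2 CPM gained by Acta2, which held 420 of the 516 CPM of the list in WT. The percentage compares gains in CPM and not folds, so its small size does not show that these genes were nearly unchanged. The share that such cells would bring is not known here. A different state of the lone WT culture, such as density or feeding at collection, cannot be told apart from genotype with 1 WT library; the DF508 libraries differed by a median log2 of at most 0.15 in these 5 lists, which is the size for 1 pair of libraries. Of the 3 ways to set 1 library against 2, only the real 1 called as many genes, 179 against at most 7 in the others, and 3 splits are too few for a share under 0.05.

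The myeloid markers in DF508 replicate 2 may come from macrophages in that culture, and the labels name no sort that would remove them. A second list of 30 macrophage genes, with no gene in any fixed list, had 25 tested members with a median log2 difference of 1.77 between DF508 replicates 2 and 1, and 20 were at least 2-fold higher. Of these members 1 was past the threshold between genotypes, Gpnmb, named after its values were seen, which fell from 542 to 327 CPM in DF508 (edgeR adjusted p = 0.0451). Of these 25 genes 15 reached 1 CPM in WT, so the cultures may share some of them. The most abundant myeloid markers, Lyz2 and Laptm5, had 2118 and 290 counts in replicate 2 against 447 and 51 in replicate 1. Both libraries carry the same genotype label, so genotype does not separate them.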
